A study of Mus musculus with 4 samples.

How the data were processed

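Gene expression was measured in the epidermis of mouse embryos at embryonic day 15.5 on the Affymetrix MOE430 array, a single-colour array of short oligonucleotides in which each transcript is read by a group of probes called a probe set. There were 4 arrays, 2 of control littermates and 2 of mutants carrying KRT14-Cre and a conditional allele of Ctnnb1 from which Cre removes exon 3. Per the labels, each array held RNA of a separate embryo. Per the labels' protocols, dorsal skin was treated with dispase to part epidermis from dermis, and the RNA was amplified in 1 cycle and labelled with biotin.

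The deposited signal intensity of each probe set on each array was the main measurement. Per the submitters' processing notes, GCOS and MAS5 were used, with no versions given in the sources used here. The deposited intensity values were on a linear scale, and their mean over all probe sets after trimming 2% at each end was 150 on every array, so the arrays had already been scaled and were not normalized again. A second table held the authors' own list of differing probe sets. Per the file headers, its values were ratios made from GCRMA expression, kept where a probe set was called Present on at least 2 of the 4 arrays and differed at least 2-fold between group means. In that deposited table each ratio was relative to the mean of the 2 controls, and the lowest ratio was 0.01. Its fold was control over mutant and was turned round here. Instrument settings of the arrays were read only to look for batches: there was 1 fluidics station, 1 scanner and 1 scan day, and each of the 4 arrays had its own fluidics module.

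Of 45101 probe sets, 64 array controls were left out, and 45037 remained. A probe set was tested where its signal lay above its array's 40th percentile on at least 2 of the 4 arrays, which left 28434 and set aside 16603 as dim. Gene names came from the platform annotation of the probes, in which 34945 probe sets named 1 gene, 932 named several and 9160 named none. Symbols were updated through the Entrez identifier with a gene table of the GRCm38.p6 assembly, which matched 34741 probe sets, or 99.4% of those naming 1 gene. No gene was named from a probe set with several. The sources used here name no genome build for the arrays, so no coordinates are given. For each of 12469 genes the probe set with the highest mean log2 signal stood for the gene, out of 23862 tested probe sets naming 1 gene. Of 6286 genes with at least 2 tested probe sets, 48 had probe sets called in opposite directions. Of 242 list genes past the threshold, 119 had another tested probe set, and 44 of these had 1 or more that did not pass.

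Log2 signals were compared with limma (version 3.58.1, in R 4.3.3) by lmFit and eBayes with an intensity trend, as mutant minus control, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. All adjusted p-values of genes are from this limma fit. Errors of log2 fold changes are standard errors of the fit over 2 arrays per group, and errors of signals are SDs. An exact two-sided permutation test of 2 against 2 arrays cannot give a p below 0.333, so the calls rest on limma's pooling of the spread over probe sets. The number of arrays limits the precision. A probe set at or below its array's 40th percentile on both arrays of a group was taken as not above background there. Its fold is given as "at least N-fold", from the brighter group's mean log2 signal and, for the dimmer group, the mean of the higher of that percentile and the measured signal on each array.

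Before the data were examined, 23 lists of 415 genes in all were fixed, some genes standing in several lists. Members were counted as rising, falling or not passing after adjustment over all genes, and again adjusted over the list alone. Lists with at least 3 measured members were tested with camera, which compares a list with all other genes, at a preset correlation of 0.01, and adjusted over the lists. Camera with an estimated correlation and fry, which tests whether the genes of a list move one way on balance, were alternatives. The genes named were also fixed by rule: the 10 rises and the 10 falls past the threshold with the largest fitted folds, which give no rank among genes below background, up to 4 members of each list with the largest moderated t, and 9 genes chosen for the mutation. Other members of the lists are named as examples chosen after their values were seen.

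The scripts were tested on simulated data with the 28434 probe sets of the comparison. Of 100 probe sets changed 2-fold, 81 were recovered, and of 100 changed 4-fold, 99 were recovered. Of 190 calls, 10 were unchanged probe sets (5.26%). Of simulated lists, 2 of 2 shifted ones and 0 of 18 unshifted ones were called. The simulated noise was drawn independently for each probe set, with an SD set by signal alone. The simulated lists thus held no correlation between genes, whereas estimates for the real lists reached 0.70 (dermal markers). These rates therefore need not hold for the real data, in which 11210 probe sets were called.

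Alternatives were quantile normalization, median centring, no filter, a filter at the 60th percentile, a pseudocount of 6, a variance model without the trend, the replicate number as a block, each array left out in turn, other thresholds, the mean of all probe sets of a gene, and the authors' table for named genes. After the data were examined, the dermal markers without control 2 and by pairs of arrays and families of genes sharing a symbol stem were added.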

Results

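Transcript levels were compared between epidermis of mouse embryos in which beta-catenin, the transcriptional effector of canonical Wnt signalling, was activated in keratin 14-expressing cells, and epidermis of their control littermates. Loss of exon 3 removes the sites at which the protein is marked for destruction. There were 2 control and 2 mutant arrays. Median signal was 26.7 and 27.6 on the controls and 30.1 and 28.6 on the mutants. The 3' to 5' signal ratio of actin, a measure of RNA integrity, was 1.17 and 1.15 in controls and 1.24 and 1.21 in mutants. Log2 signals correlated across probe sets at 0.972 between the controls and 0.970 between the mutants, against 0.813 to 0.815 between groups. Probe sets are not independent replicates. Within groups 4.64% and 4.86% of probe sets differed over 2-fold, and between groups 23.8% to 24.3%.

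In mutant epidermis 29 of 31 measured hair shaft and inner root sheath genes and 20 of 22 Wnt target and feedback genes were higher than in control littermates. Of 36 epidermal differentiation genes 25 were lower and 6 higher. As lists, these passed camera with a preset correlation and not with an estimated one (adjusted p = 0.284, 0.284 and 0.355). The estimated form takes its p from few residual degrees of freedom, so not passing it cannot decide against a list. With fry, which does not compare a list with other genes, adjusted p was 4.15e-03, 4.33e-03 and 4.97e-03. Krt31, a hair shaft keratin, was at least 571-fold higher. Axin2, a feedback inhibitor and target of Wnt signalling, rose by 2.31 ± 0.09 on the log2 scale (SE, n = 2 per group). Krt10 and Lor, a keratin and a cornified envelope protein of the suprabasal layers, fell by 3.57 ± 0.11 and by 4.08 ± 0.13. Of 12469 genes tested, 5622 changed at the threshold, with 2565 higher and 3057 lower in the mutant. Fitted folds were at least 2-fold for 2596 genes, 1340 higher and 1256 lower, and at least 16-fold for 225 higher and 106 lower. With the 590 changed genes that were below background in a group taken at their bound, 1253 were at least 2-fold higher and 1182 lower, and 133 were at least 16-fold higher and 54 lower. At the level of probe sets, 11210 of 28434 (39.4%) changed, 5386 upward and 5824 downward. Of these, 5456 were at least 2-fold by fitted fold, or 5037 with bounds, and 5754 were under 2-fold by fitted fold.

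**Figure D1:**
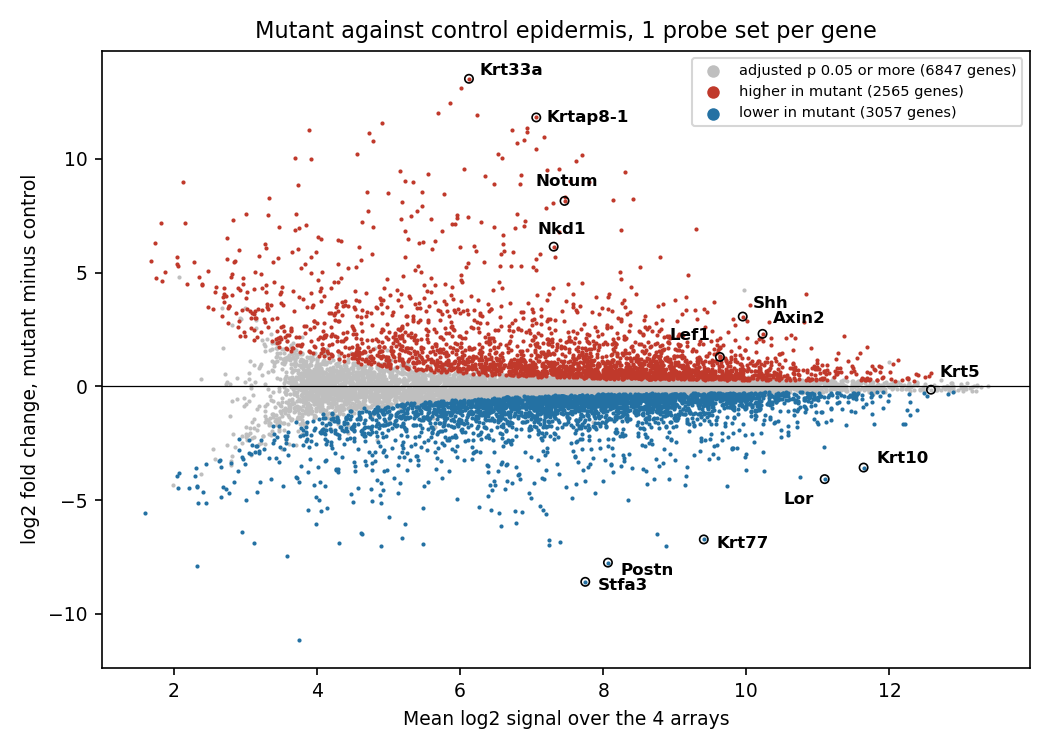
Log2 fold change (mutant minus control) of each of 12469 genes against its mean log2 signal over the 4 arrays, with genes past the threshold in red (2565 higher) or blue (3057 lower) and the rest in grey. Krt33a lies highest, and Krt77, Lor and Krt10 fell from high signals; folds of genes below background in a group are drawn as fitted, not as bounds.

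The mutated gene and the mouse keratin 14 gene were examined first. Ctnnb1 signal rose by 0.47 ± 0.08 on the log2 scale, from 5126 ± 263 to 7115 ± 294 (SD, n = 2; limma adjusted p = 3.06e-03), and its other probe sets rose by 0.89 and 0.72; the first call was lost in a fit without the intensity trend. A probe set outside exon 3 does not check the genotype. The signal of Krt14 does not measure expression of KRT14-Cre. Krt14, the mouse keratin 14 gene, had a signal of 5573 ± 43.7 in controls and 4400 ± 587 in mutants. Its other probe sets fell by 0.45 ± 0.13 (adjusted p = 0.0242) and by 1.75 ± 0.32 (adjusted p = 3.66e-03). The fall of -0.35 ± 0.10 (adjusted p = 0.0303) of the brightest was no longer past the threshold without control 1, without control 2, without mutant 1, without the filter on dim probe sets or without the intensity trend. Nkd1, a Wnt feedback inhibitor, rose by 6.14 ± 0.15, from 18.9 to 1332, and Lef1, a DNA-binding partner of beta-catenin, by 1.29 ± 0.10. The control signal of Nkd1 lay little above the controls' 40th percentiles (14.4 and 14.6), so the size of its fold is uncertain.

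The 10 rises taken by fitted fold were of hair keratin or keratin-associated protein genes, the latter encoding the matrix between hair keratin filaments. Each was below background in both controls, so that their fitted folds and this choice give no rank, and the bound of Krt31 exceeded each of theirs. Krtap8-1 was at least 555-fold, Krt33a at least 522-fold, Krtap22-2 at least 432-fold and Krtap11-1 at least 416-fold higher. Krtap16-3, Krtap1-5, Krtap6-5 and Krtap15 were at least 363-fold, 326-fold, 302-fold and 228-fold higher. Krtap9-3 was at least 114-fold and Krtap19-3 at least 50.8-fold higher. Of the 10 falls taken by fitted fold, all but Postn and Gpx3 were below background in both mutants and likewise have no rank. Krt77 and Casp14, above background in both groups and outside these 10, were 106-fold and 48.9-fold lower, more than the bounds of Clca3a2, Lrig1, Slc15a3, Hcar2, Slc22a4 and Skint10. Among the 10, Stfa3 was at least 268-fold, Sdr16c5 at least 108-fold and Clca3a2 at least 40.2-fold lower in the mutant. Postn, a secreted matrix protein, fell by 7.75 ± 0.38, from 3946 to 20.5, and Gpx3, a secreted glutathione peroxidase, fell by 7.01 ± 0.27, from 5382 to 43.8. Postn signal in mutant 1 (11.3) lay below that array's 40th percentile (16.1), so the size of its fold is uncertain. Lrig1, a receptor inhibitor of the epidermis, was at least 31.2-fold lower, and another, dim probe set of this gene had a value of 0.74 (adjusted p = 0.151). In the authors' deposited table this probe set of 31.2-fold and a further one were 100-fold and 99.97-fold lower, with both mutants at the lowest ratio, 0.01. Slc15a3, Hcar2 and Slc22a4 were at least 21.3-fold, 13.6-fold and 10.1-fold lower. Skint10 was at least 4.92-fold lower (adjusted p = 8.84e-04), a call lost without control 1 and without control 2.

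Wnt target and feedback genes rose together. Of 22 measured members 20 rose, 0 fell and 2 did not pass, and 20 rose when adjusted over the list alone. Notum, a secreted Wnt deacylase, was at least 205-fold higher. Wif1 and Dkk4, secreted Wnt inhibitors, rose by 4.90 ± 0.14 and 3.60 ± 0.11, and Apcdd1 by 2.22 ± 0.08. Lgr5 (-0.32 ± 0.69) and Myc (-0.07 ± 0.11) did not pass. The list's median was 1.91 and its camera adjusted p was 1.49e-12, with adjusted p = 0.284 with an estimated correlation. Among 27 Wnt ligands, receptors and secreted inhibitors, 15 rose, 5 fell and 7 did not pass; adjusted over the list alone, 16 rose and 5 fell. Wnt5a was at least 39.9-fold higher and Wnt10a rose by 1.73 ± 0.11, whereas Wnt7b fell by 1.82 ± 0.11 and Sfrp1 by 2.21 ± 0.32. This list had a median of 0.53 and a camera adjusted p of 4.52e-03, with adjusted p = 0.284 with an estimated correlation.

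**Figure D2:**
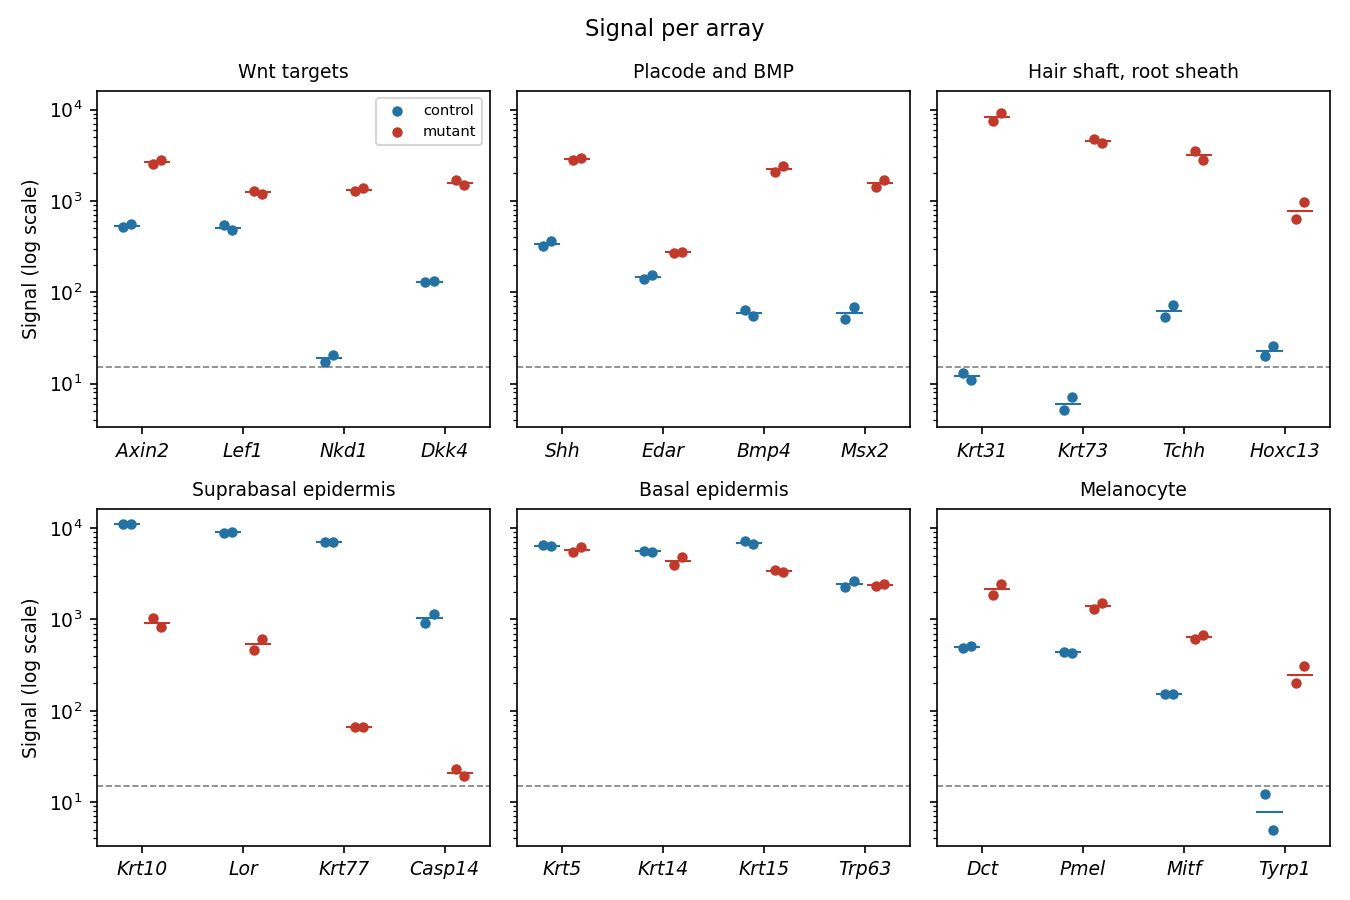
Signal of each array on a log scale for genes of 6 groups, with controls in blue, mutants in red, a short line at the geometric mean of 2 arrays and a dashed line at the mean of the arrays' 40th percentiles. Axin2 lies near 539 in controls and 2671 in mutants, while Krt10 lies near 10989 and 931.

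Hair placode genes, which mark the epithelial thickening that begins a follicle, rose in the greater part. Of 28 measured, 18 rose, 6 fell and 4 did not pass, and adjusted over the list alone 19 rose and 7 fell. Shh, a placode morphogen, rose by 3.07 ± 0.10, from 342 to 2867, and Bmp2 by 3.69 ± 0.13. Edar, the ectodysplasin receptor, rose by 0.89 ± 0.13. Among the falls were Bcl11b (-1.07 ± 0.12) and Ltb, at least 4.32-fold lower. The median was 0.80 and camera's adjusted p was 5.55e-05, with adjusted p = 0.284 with an estimated correlation. BMP and activin genes gave 16 rises, 2 falls and 3 not passing of 21, or 17 rises and 3 falls adjusted over the list alone. Bmp4 rose by 5.24 ± 0.13, and Msx2, a transcription factor downstream of BMP, by 4.71 ± 0.17, while Bmpr1b fell by 1.87 ± 0.26. The median was 1.88, or 0.95 with bounded genes at their bound, and camera's adjusted p was 3.61e-07, with adjusted p = 0.284 with an estimated correlation. Of 15 FGF pathway genes 13 rose, 1 fell and 1 did not pass, with 13 and 2 adjusted over the list alone. Fgfr1 rose by 2.45 ± 0.17 and Etv4, a transcription factor induced by FGF, by 2.77 ± 0.24. Another probe set of Etv4 had 1.20 ± 0.42 (limma adjusted p = 0.0549) and did not pass. The fall, of Fgfr2 (-0.41 ± 0.13), was lost without control 1 and without control 2. The list's median was 1.32 and its camera adjusted p was 2.09e-05, with adjusted p = 0.284 with an estimated correlation.

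Hedgehog, ectodysplasin and Notch genes moved in both directions. Of 11 hedgehog genes 4 rose, 4 fell and 3 did not pass, and adjusted over the list alone 4 rose and 5 fell. Gas1, a hedgehog co-receptor, fell by 3.51 ± 0.17 and Cdon, another, by 1.52 ± 0.14, while Gli1, a hedgehog target, had 0.15 ± 0.12 and did not pass. The 4 rises were of Shh (3.07), Smo (1.09), Gli3 (0.59) and Ptch1 (0.56). Smo, Gli3 and Ptch1 each had another probe set that did not pass, that of Ptch1 with 0.019 ± 0.27 (limma adjusted p = 0.964). The median was 0.15, the mean -0.32 and camera's adjusted p 0.927. Of 14 ectodysplasin and NF-kappaB genes 3 rose, 9 fell and 2 did not pass, the same counts of rises and falls as adjusted over the list alone. Birc3 fell by 1.70 ± 0.18 and Eda was at least 3.39-fold lower. The falls were 5 without control 2, and camera's adjusted p was 0.350. Of 14 Notch genes 3 rose, 6 fell and 5 did not pass, with 4 and 6 adjusted over the list alone. Heyl rose by 4.25 ± 0.21 and Nrarp fell by 1.10 ± 0.08. The median was -0.36, the mean 0.18 and camera's adjusted p 0.607. With genes at their bound the median was -0.26, and without the filter on dim probe sets it was -0.10 over 16 genes.

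Hair shaft and inner root sheath genes rose almost throughout. Of 31 measured, 29 rose and 2 fell, and the counts were the same adjusted over the list alone. Krt33b was at least 446-fold higher, and Krt73, of the inner root sheath, at least 315-fold higher. Tchh, trichohyalin, rose by 5.67 ± 0.17, and Hoxc13 and Foxn1, transcription factors needed for hair keratin expression, by 5.11 ± 0.23 and 2.70 ± 0.12. Gata3 fell by 1.69 ± 0.13 and Selenbp1 by 0.79 ± 0.14. The median was 6.96, or 5.86 with 15 genes at their bound, and camera's adjusted p was 2.30e-20, with adjusted p = 0.284 with an estimated correlation.

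Epidermal differentiation genes fell. Of 36 measured, 25 fell, 6 rose and 5 did not pass, and the rises and falls were the same adjusted over the list alone. Krt77, a suprabasal keratin, fell by 6.73 ± 0.09, from 6985 to 65.9. Casp14, a protease of cornifying cells, fell by 5.61 ± 0.17, though another of its probe sets had -0.32 ± 0.24 (adjusted p = 0.316) and did not pass, and Krt1 fell by 3.98 ± 0.12. The genes that rose were Krt80 (2.21 ± 0.15), Cst6 (1.59 ± 0.24), Cdsn (3.42 ± 0.68), Tgm3 (0.64 ± 0.12), Sprr1a (0.72 ± 0.17) and Rptn, at least 1.61-fold higher. Another probe set of Tgm3 had 0.27 ± 0.21 (limma adjusted p = 0.335) and did not pass. Without the intensity trend the rises were 3. The median was -1.32 and camera's adjusted p was 5.17e-07, with adjusted p = 0.355 with an estimated correlation. Of 17 basal keratinocyte and hemidesmosome genes 7 rose, 6 fell and 4 did not pass, with the same rises and falls adjusted over the list alone. Krt15 fell by 1.03 ± 0.08 and Lamb3, a laminin chain, rose by 1.26 ± 0.13, while Krt5 (-0.15 ± 0.09) and Trp63 (-0.04 ± 0.10) did not pass. The falls were 3 without control 1 and 3 without control 2, and camera's adjusted p was 0.607.

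**Figure D3:**
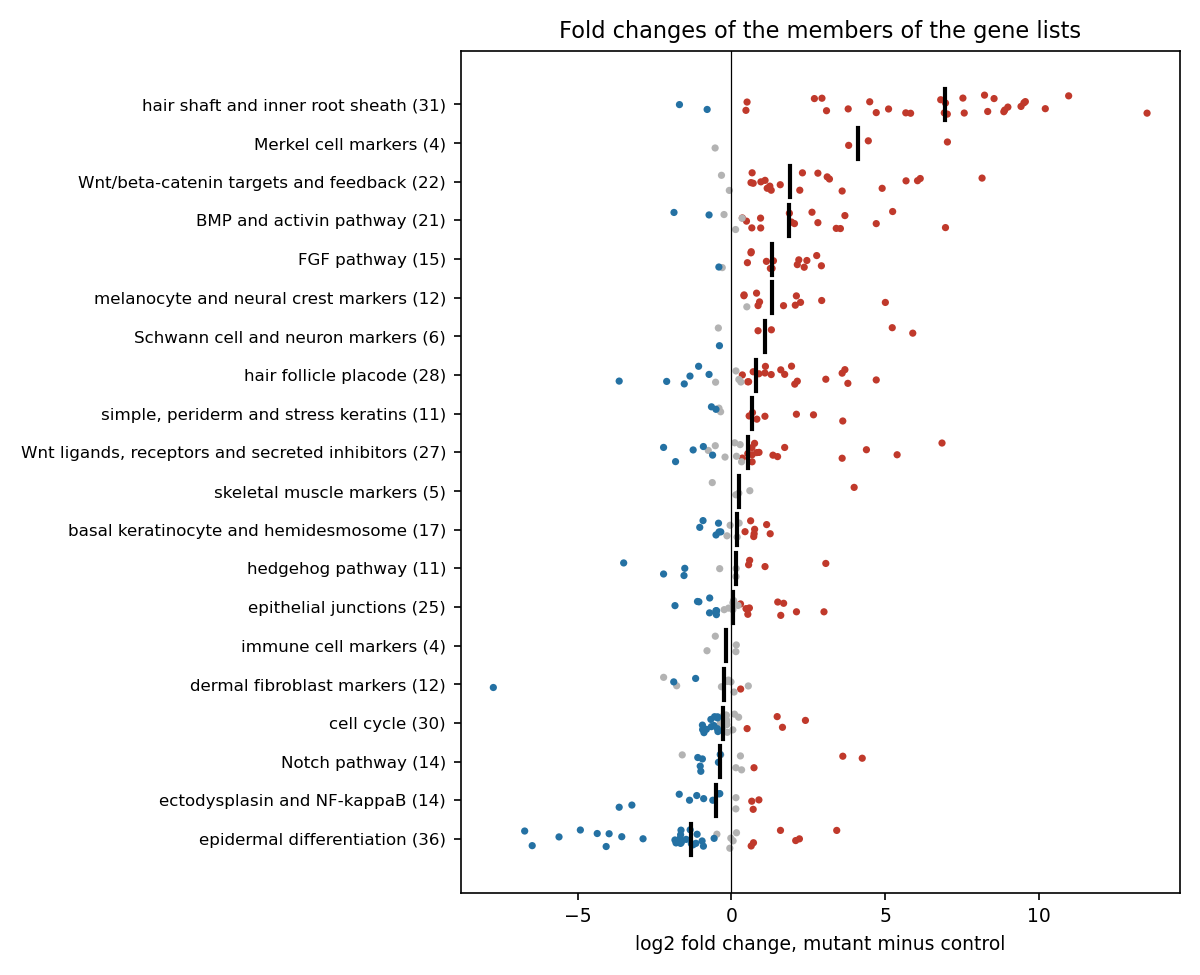
Log2 fold change (mutant minus control) of each measured member of the lists with at least 4 measured members, the number in brackets, with rises past the threshold in red, falls in blue and the rest in grey; the black bar is the list's median and vertical scatter within a list has no meaning. Hair shaft and inner root sheath genes have the highest median, 6.96, and epidermal differentiation genes the lowest, -1.32.

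The lists of simple, periderm and stress keratins, junction genes and cell cycle genes did not pass camera. Of 11 keratins 7 rose, 2 fell and 2 did not pass, with 7 and 4 adjusted over the list alone. Krt6b rose by 3.62 ± 0.40 and Krt16, a keratin of stressed epidermis, by 2.67 ± 0.21. The falls were 0 without control 2 and 0 without mutant 2, 4 without mutant 1 and with median centring, and 1 with quantile normalization; camera's adjusted p was 0.0619. Of 25 junction genes 10 rose, 9 fell and 6 did not pass, with 10 and 9 adjusted over the list alone. Cldn6, a claudin, rose by 3.01 ± 0.16 and Cdh3, P-cadherin, by 1.60 ± 0.12, while Cdh1, E-cadherin, fell by 0.71 ± 0.08 and Dsc3, a desmocollin, by 1.11 ± 0.09. Another probe set of Cdh3 had 0.65 ± 0.22 (limma adjusted p = 0.0508) and did not pass. Camera's adjusted p was 0.607. Of 30 cell cycle genes 4 rose, 12 fell and 14 did not pass, with 5 and 14 adjusted over the list alone. The inhibitors Cdkn1a and Cdkn2b rose by 1.49 ± 0.11 and 1.66 ± 0.13, and Bub1b, a spindle checkpoint kinase, fell by 0.89 ± 0.12. The median was -0.28 and camera's adjusted p was 0.0647. The list held inhibitors beside genes of cell division, so camera did not test a shift of the latter alone.

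Markers of other cell types were measured on the same arrays. Of 12 melanocyte and neural crest genes 11 rose and 1 did not pass, and 12 rose adjusted over the list alone. Dct, a melanin synthesis enzyme, rose by 2.11 ± 0.14, Mitf, the melanocyte transcription factor, by 2.08 ± 0.12 and Mlana by 2.94 ± 0.17. The median was 1.30 and camera's adjusted p was 2.41e-06, with adjusted p = 0.355 with an estimated correlation. Of 12 dermal fibroblast genes 1 rose, 3 fell and 8 did not pass, with the same rises and falls adjusted over the list alone, a median of -0.23, a mean of -1.20 and a camera adjusted p of 0.304. The median was -1.32 without control 1, -1.14 without mutant 2, 0.050 without control 2 and 0.0031 without mutant 1, so its sign rested on single arrays. Postn and Col5a1 (-1.17 ± 0.20) fell. Postn signal was 3590 in control 1 and 4302 in control 2, while Col1a1 and Col3a1 were 57.9-fold and 16.6-fold higher in control 2. Postn thus did not follow these collagens, and its fall alone does not show a loss of dermal cells. The fall of Col1a2 (-1.88 ± 0.49) was lost without control 2, without mutant 1 and without the intensity trend, and the rise of Dcn (0.30 ± 0.08) was lost without either control, without mutant 2, with median centring, without the filter on dim probe sets and without the intensity trend. Col3a1 signal was 22.9 in control 1 and 381 in control 2, against 26.6 and 27.8 in the mutants, and Col1a1 signal was 1.84 in control 1 and 107 in control 2, against 6.65 in mutant 1 and 63.2 in mutant 2. Lum signal was likewise higher in control 2 (59.3) and mutant 2 (39.9) than in control 1 (12.4) and mutant 1 (11.8).

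Of 6 Schwann cell and neuron genes 4 rose, 1 fell and 1 did not pass, with 4 and 1 adjusted over the list alone. Among the rises was Sox10 (0.87), which stands in the melanocyte list too. Other probe sets of Sox10 had 0.28 and 0.60 (limma adjusted p = 0.407 and 0.224) and did not pass. Tubb3, a neuronal tubulin, rose by 5.23 ± 0.20, and camera's adjusted p was 0.101. The signal of Tubb3 in controls (25.7 and 17.3) was near their 40th percentiles (14.4 and 14.6), so the size of its fold is uncertain. Erbb3 fell by 0.39 ± 0.10, a call lost without control 1, control 2 or mutant 2. Of 4 measured Merkel cell genes 3 rose and 1 did not pass, with 3 adjusted over the list alone. Piezo2, a mechanically gated channel, was at least 9.02-fold higher on 1 probe set, while another had 0.58 ± 0.32 (adjusted p = 0.191) and did not pass. The rise of Tmem163 was lost without either mutant, and Atoh1 (-0.53 ± 0.51) did not pass. The median was 4.13, or 1.94 with genes at their bound, and camera's adjusted p was 0.0619. Without the filter on dim probe sets the list held 10 genes, with a median of 0.24 and an adjusted p of 0.546. Of 4 immune genes 0 passed with limma (camera adjusted p = 0.751), and Csf1r (-0.80 ± 0.35) passed without mutant 2. Of 5 muscle genes 1 rose, Tnnt1, at least 1.82-fold, a call lost without mutant 2 (camera adjusted p = 0.553). Adjusted over the list alone the counts were 0 immune genes, 1 muscle gene, 0 endothelial genes, 1 erythroid gene and 0 sex-linked genes. The 2 measured endothelial genes, the 1 erythroid gene, Hbb-y (adjusted p = 0.0539), and the 1 sex-linked gene tested, Xist, did not pass over all genes, and these lists were too small for camera. Hbb-y, at least 1.54-fold higher, passed without control 1, without control 2, with the pseudocount, with the replicate block and as the mean of its probe sets.

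Xist, the transcript of the inactive X chromosome, gave a signal of 4952 in control 1, 4245 in mutant 1 and 4404 in mutant 2 and of 10.9 in control 2. The Y-linked gene Eif2s3y gave 436 in control 2 and at most 2.71 on the other arrays. Xist had a log2 fold change of 4.22 ± 2.26 (adjusted p = 0.179) and passed with the replicate block and without control 1.

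The authors' deposited table of differing probe sets was compared with the fitted folds. It was made from these arrays and is not independent evidence. It held 6296 probe sets of 3583 genes, 3124 higher in control and 3172 higher in mutant. The difference of mean log2 signals had the same direction for 6293 (99.95%) and the opposite for 3. Of 6278 that were tested, 5802 (92.4%) were past the threshold in the same direction. Of the 5456 probe sets changed at least 2-fold here by fitted fold, 4568 (83.7%) were in the authors' deposited table. Log2 folds of the authors' deposited table and of the signals correlated across probe sets with Pearson's r of 0.954 and Spearman's rho of 0.959. The Xist probe sets in the authors' deposited table (3 in all) were 9.26-fold, 4.85-fold and 12.2-fold higher in mutant, owing to control 2 (0.010, 0.032 and 0.010). Control 1 (2.00, 1.97 and 2.00) lay above both mutants on each of them (1.38 and 1.25, 1.37 and 1.09, 1.85 and 1.62).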

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

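The tests of an exchanged label, of dermal carry-over, of the share of melanocytes and of cross-hybridization were chosen only after the result was seen; those of embryo sex and of scaling were chosen before.

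Of 19 mouse control probe sets that no comparison used, 2 were higher on both mutant arrays than on both controls, with group means at least 1.5-fold apart. The probe set at the 3' end of 18S ribosomal RNA was 4.74-fold higher in mutant, with signals of 79.7 and 28.4 in controls and 120.03 and 423 in mutants, or 2.52-fold higher without mutant 2. The other 18S probe sets were 2.98-fold and 2.42-fold higher, with mutant 1 below control 1 on both (160.9 against 166, and 51.4 against 63.8). A probe set of a mouse B2 repeat was 1.59-fold higher, with signals of 265 and 293 in controls and 459 and 428 in mutants, while another B2 probe set was 1.08-fold higher. The 4 pyruvate carboxylase probe sets were 1.97-fold to 3.61-fold lower on the mutant arrays.

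Control 2 lacked Xist and held Eif2s3y. An exchanged label would give this array the hair keratin signal of a mutant, but over the 31 measured hair shaft genes its median log2 difference from control 1 was 0.289, against 7.02 and 7.17 for the mutants. Both other Y-linked genes measured, Kdm5d and Uty (2 of 2), had a probe set in which control 2 was at least 16.4-fold and 14.0-fold above every other array, with the others taken at their 40th percentile. Control 2 may therefore be the only male embryo, which leaves sex unbalanced between the groups.

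Melanocyte genes were higher in mutant epidermis (median 1.30, or 1.33 without control 2), and scaling is argued against by their lowest median under another scaling, 1.19. Dermis carried over into the mutant samples is argued against by the upper quartile of the fibroblast genes, 0.00839, or 0.416 without control 2 and 0.576 (melanocyte median 1.44) for mutant 2 against control 1 alone. A larger share of melanocytes would raise their pigment genes alike, and the log2 folds of Pmel, Dct, Tyr and Slc45a2 were apart in 4 of 6 pairs as deposited (95% Bonferroni intervals) and in 1 of 6 after each array's 60th percentile was subtracted as unspecific signal, Dct above Tyr by 1.02 (interval 0.11 to 1.93). Tyrp1 (at least 17.2-fold) and Mlana (7.65-fold) rose by more than Dct (4.32-fold) but were under the test's limit, the 60th percentile of mutant 1 (58.6), although the control mean of Mlana, 58.4, was above the controls' own percentiles (54.7 and 56.2). The test took 4 forms with the values in view, of which the earlier 3 spoke against a larger share as the whole cause; it is left open because the amount of unspecific signal is unknown.

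Hair keratin and keratin-associated protein genes rose together. Of the 13 measured members of the hair shaft list that are not keratins, 11 rose, which does not bear on shared signal among keratin probe sets, and that was not tested. For single keratin-associated protein genes, 33 of 35 tested rose, and 30 of the 32 whose probe set names mark no shared probes. Without probe sequences, signal of each member and signal of its close relatives cannot be told apart, so levels of single members of this family stay uncertain.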

How the results depend on the processing

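These alternatives were chosen before the data were examined, and the dermal markers without control 2 and by pairs of arrays and the symbol families, given in the other parts, after. Of 1306 recomputed values of 103 named genes, 1267 kept their direction and side of the threshold, 21 passed no longer, 8 passed newly and 10 changed sign. None of the 10 was past the threshold before or after the change, and the cause was not tested. With an array left out, Kdr ranged from -0.74 to 0.27, Egfl7 from -0.15 to 0.029, Lyz2 from -0.66 to 0.95, Atoh1 from -1.11 to 0.046, Ckm from -1.30 to 0.055, Mylpf from -0.023 to 0.31 and Xist from -0.20 (without control 2) to 8.63 (without control 1, where it passed). With the mean of its probe sets Laptm5 had -0.99. The count of 11210 probe sets was 11222 with quantile normalization and 11523 with median centring, where the median gene shifted from -0.056 to -0.167 and 38.7% rather than 48.0% of the calls were upward. It was 8310 without the intensity trend and 8280 to 9594 with an array left out, where the lone array of a group is assumed to vary like the others. Without the trend, differentiation genes gave 3 rises, basal genes 2 falls, simple keratins 4 rises and 0 falls, junction genes 6 rises and 5 falls and cell cycle genes 6 falls. With at least 2-fold change by fitted fold 5456 probe sets and 2596 genes were left, or 5037 and 2435 with those below background in a group at their bound. Of the authors' probe sets at 3-fold or more, 100% had the same direction. With an estimated correlation the lists of Wnt targets, Wnt ligands, placode, BMP, FGF and hair shaft genes had an adjusted p of 0.284. Those of differentiation and melanocyte genes had 0.355, so no list passed this form. With fry, which asks a different question, the same lists had adjusted p from 4.15e-03 to 0.0101. The estimated correlations come from few degrees of freedom. For Wnt ligands the estimate was -0.0057, below the preset 0.01, yet camera's unadjusted p rose from 1.81e-03 to 0.0727. For Merkel genes (-0.297) it rose from 0.0309 to 0.160, and for Schwann cell genes (-0.135) from 0.0608 to 0.195. These values argue against a correlation above the preset as the cause for these lists, and no other cause was tested.

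Some lists past no threshold passed under an alternative; the cause was not tested. With fry, which asks a different question, adjusted p was 0.0489 for ectodysplasin, 0.0497 for simple keratins, 4.33e-03 for junctions, 4.15e-03 for Merkel and 6.18e-03 for Schwann cell genes. With median centring it was 0.0392 for simple keratins and 0.0287 for Merkel genes, with the pseudocount 0.0403 for Merkel genes, and without a filter 0.0207 for cell cycle genes. Merkel genes had 0.546 without a filter, where 10 rather than 4 were measured. With an array left out it ranged from 0.0113 to 0.123 for simple keratins, from 0.0299 to 0.145 for cell cycle genes, from 0.0170 to 0.663 for dermal, from 0.0170 to 0.129 for Merkel and from 0.0299 to 0.129 for Schwann cell genes. The direction of the hedgehog list, past no threshold, turned without a filter (adjusted p = 0.872), with the block (0.847), with the mean of probe sets (0.705) and without control 1 or mutant 1 (0.926 to 0.998 with an array left out). That of the immune list turned without a filter (0.872) and without mutant 1 (0.529 to 0.905 with an array left out). The dermal list passed without control 1 and without mutant 2.

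The replicate number as a block gave 11525 probe sets, of which 10883 were shared. It gave an adjusted p of 0.0244 for simple keratins, 0.0498 for Merkel and 0.0476 for Schwann cell genes. The within-group differences of the same numbers correlated at 0.0145 over probe sets, so little was shared over all of them. This cannot exclude a difference shared by a subset of genes. Col1a1 and Lum, for example, were higher on both arrays numbered 2, while Dcn and Vim were not. A filter by Present calls and a batch block were not run, because no calls per array were used here and each array had its own module. The authors' table was not used for counts or lists, because it holds preselected probe sets. Signal over background limits the folds of genes dim in a group to bounds.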

Other observations

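The test of symbol families was chosen only after the data were seen. Of 199 families of at least 8 tested genes, 3 passed camera at the preset correlation. Keratin-associated protein genes rose in 33 of 35 (adjusted p = 2.43e-21), keratins gave 29 rises and 7 falls of 43 (adjusted p = 2.43e-07), and genes with the stem Bmp 6 rises and 1 fall of 9 (adjusted p = 0.0192). With an estimated correlation all 3 had an adjusted p of 0.981. That form rests on few residual degrees of freedom, so this cannot decide against them. Aldehyde dehydrogenases, which oxidise aldehydes, gave 1 rise and 10 falls of 15, and Hoxb genes 6 rises and 0 falls of 8, each with adjusted p = 0.0556, past no threshold.

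Single genes outside the naming rule are given as values chosen after they were seen. Gsta2, a glutathione transferase, fell by 6.83 ± 0.15 and Gstt3, another, fell by 4.52 ± 0.16. Hoxc4, Hoxc5, Hoxc6 and Hoxc8 had log2 fold changes of -2.84 ± 0.14, -2.20 ± 0.22, -1.05 ± 0.18 and -1.74 ± 0.16, while Hoxc13 of the same cluster rose by 5.11 ± 0.23. S100a3, a calcium-binding protein of the hair cuticle, rose by 8.21 ± 0.13, from 16.5 to 4863. Its control signal lay little above the controls' 40th percentiles (14.4 and 14.6), so the size of this fold is uncertain.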
